A study of Mus musculus with 8 samples.

How the data were processed

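Gene expression was measured by RNA sequencing in 8 libraries that the labels' protocols trace to lungs of KP mice, in which inhaled adenovirus carrying Cre recombinase switches on an oncogenic Kras allele and deletes Trp53 so that lung tumours form. The sample labels give the cell type as CD8+ T cell, sorted from the tumour-bearing lungs, and the treatment as PBS, PD-1Ab, PD-1Ab7 or Flt3L plus PD-1Ab7, with 2 libraries per treatment. The genotype label of all 8 libraries is WT, and the labels do not say how that relates to the KP alleles. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.3a and featureCounts were used, and GRCh38 and GRCm38 are listed as genome builds. The aligner settings, the annotation, whether strand was used in counting and any handling of molecular identifiers are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, as are gene families with similar members such as immunoglobulin V segments and MHC class I genes.

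The deposited table holds RPKM (reads scaled by gene length and library depth), per the file headers, for 39083 gene rows and 8 libraries. Of these rows, 26 carry a date in place of a gene symbol and 4 share their name with another row. The exon length of each gene was taken from GENCODE M21 on GRCm38, whose symbols matched 37115 rows. RPKM multiplied by that length gave whole multiples of a per-library unit, within a tolerance of 0.05 read, for 92.4% to 92.9% of values up to 200 reads. The number of reads that scales each library was recovered from that unit. The recovered number came to 47770550 and 53255862 reads for PBS, 55479128 and 53652799 for PD-1Ab, 54296999 and 58539981 for PD-1Ab7, and 57782719 and 50557025 for Flt3L plus PD-1Ab7. The recovered reads of all rows sum to 1.10 times that number in each library. That ratio does not depend on the recovered number, so it does not test it. If the recovered numbers hold, counting error is small for all but low genes.

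Tests used log2(RPKM + 1) for the 15868 rows with at least 1 RPKM in at least 2 libraries. A fold change on this scale understates the change of low genes. The linear model of limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance, had 1 coefficient per group and took all 8 libraries, so that the 4 groups share 4 residual degrees of freedom. It was two-sided with Benjamini-Hochberg adjustment over all genes, and genes with an adjusted p under 0.05 are called changed. In all, 6 comparisons were made: each treatment against PBS and the treatments against each other. A count of genes that also changed at least 2-fold was chosen after seeing the data. Gene lists, 24 in all, were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated. The estimated form refers to only the 4 residual degrees of freedom, so a list can lose its call for that reason alone. The lists cover T cell identity, cytotoxic effectors, inhibitory receptors and exhaustion, naive, memory and stem-like genes, tissue residency, proliferation, interferon-stimulated genes, MHC class I presentation, immediate early and heat shock genes, chemokine and cytokine receptors, costimulation, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, and markers of B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells and MHC class II, CD4 and regulatory T cells, NK and gamma-delta T cells, lung epithelium and tumour, endothelium and fibroblasts, and red cells. Lists, tests, comparisons and the rule for named genes were fixed before the data were examined.

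The rule for named genes took, per comparison, up to 10 genes with the largest rise and up to 10 with the largest fall among called genes whose libraries do not overlap between the groups, leaving out predicted and clone names. It added up to 4 members of each list with the smallest p, and a fixed set of T cell, chemokine receptor and cytokine genes. Genes whose levels are given outside the comparisons were chosen from general knowledge of cell types, some of them after their values were seen. Gene positions are from GENCODE M21 on GRCm38.

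The depth, model and list steps were tested on simulated data. All 8 libraries were simulated around the mean over all groups, with a spread of 2% beyond counting error. In 1 group, 200 genes were changed, an equal number at each fold size. With PD-1Ab changed and compared with PBS, the model recovered 83.7% of 2-fold, 52.0% of 1.5-fold and 18.0% of 1.25-fold changes. It recovered 0% of 1.1-fold changes. Of 14842 genes, 83 were called, with 7 false calls. With Flt3L plus PD-1Ab7 changed and compared with PBS, the shares were 74.5%, 68.0%, 33.3% and 0%. Of 14834 genes, 86 were called, with 1 false call. Both simulations used the same means, so these shares differ by the random draw and not by treatment. The PBS libraries had a larger spread (3.05%) and far more genes changed in the data, so these rates may not carry over. Camera called the raised list and 0 of 20 unchanged lists. The simulated genes varied independently, whereas the estimated correlation in the data reached 0.20 (glycolysis). This test therefore does not show how camera handles correlated lists. Alternatives covered the pseudocount, the filter, 3 other scalings, a robust prior variance, fits of 2 groups alone, the replicate number as a block and leaving out each library. A limma-voom fit on the recovered reads of 12800 genes, 80.7% of those tested, with whole reads in all 8 libraries, was added after seeing the data. Alternatives planned for a table of counts were not run because the table holds RPKM. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.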

Results

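RNA sequencing compared 4 treatments in 8 libraries labelled CD8+ T cell, with 2 libraries per treatment. The labels' protocols describe KP mice with lung tumours, while the genotype label of all 8 libraries is WT. PBS is the control. PD-1, which PD-1Ab and PD-1Ab7 are named for, is an inhibitory receptor of T cells. Flt3L is the ligand of Flt3, a growth factor receptor that drives dendritic cell development. The labels do not say how PD-1Ab7 differs from PD-1Ab. The series title names the chemokine CCL7 beside Flt3L, and cDC1 (type 1 conventional dendritic cells) and T cell activation as subjects. Depth was 47770550 to 58539981 reads per library. The 2 libraries of a group correlated at 0.9947 to 0.9955 across genes and libraries of different groups at 0.9514 to 0.986. After counting error, the spread between the 2 libraries of a group was 1.37% for Flt3L plus PD-1Ab7, 2.28% for PD-1Ab, 2.69% for PD-1Ab7 and 3.05% for PBS, over genes of high depth. Nothing in the labels says that the 2 libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The first 3 principal components held 53.8%, 25.7% and 10.2% of the variance.

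In every library, transcripts of macrophages and lung epithelium were more abundant than those of T cells. Lyz2, a lysozyme of macrophages and alveolar type II cells, lay at 2764 to 5616 RPKM and ranked 3 to 7 among all genes. Sftpc, the surfactant protein of alveolar type II cells, lay at 815 to 2205 RPKM and Scgb1a1, the secretoglobin of airway club cells, at 732 to 3945 RPKM. The T cell receptor subunit Cd3e (chromosome 9, 44998740 to 45009627) lay at 3.04 to 9.04 RPKM. Cd8a (chromosome 6, 71373427 to 71379173) lay at 4.13 to 13.3 RPKM and Cd8b1 (chromosome 6, 71322788 to 71337494) at 17.9 to 62.3 RPKM, while Cd4 ranged from 6.08 ± 0.236 RPKM in Flt3L plus PD-1Ab7 to 11.8 ± 0.244 RPKM in PBS (SD, n = 2) and Foxp3, the regulatory T cell factor, lay at 3.30 to 4.79 RPKM. Xcr1, the chemokine receptor of cDC1, lay at 0.357 to 0.783 RPKM and Clec9a, another cDC1 receptor, at 6.88 to 19.0 RPKM. The median macrophage marker had 50.5 ± 3.30 RPKM in PBS, 34.3 ± 0.970 in PD-1Ab, 41.6 ± 1.50 in PD-1Ab7 and 64.9 ± 2.70 in Flt3L plus PD-1Ab7 (SD, n = 2). The level of the middle marker differs in direction from the genes of the list, of which 4 rose and 12 fell of 22 in Flt3L plus PD-1Ab7 against PBS, with a median log2 fold change of -0.17. The median T cell identity gene had 14.6 ± 0.0920, 17.6 ± 0.530, 14.7 ± 0.130 and 7.38 ± 0.0720 RPKM in the same order. Changes of a gene below are changes in these mixed libraries.

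**Figure D1:**
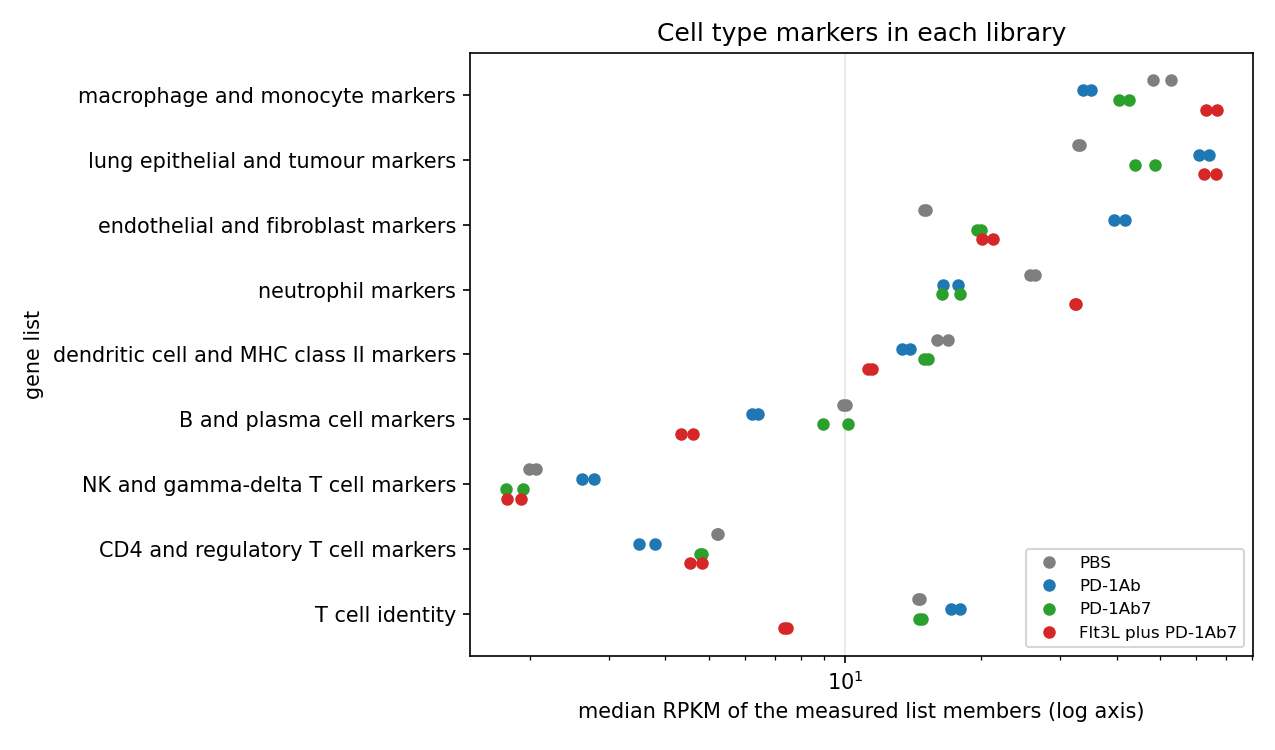
Median RPKM of the measured members of 9 marker lists on a log axis, with a point for each of the 8 libraries coloured by treatment. Macrophage, epithelial and endothelial or fibroblast lists lie above the T cell identity list in the same treatment, and the T cell identity list has its lowest medians, near 7.38 RPKM, in Flt3L plus PD-1Ab7.

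PD-1Ab was compared with PBS to ask what it changed in the absence of Flt3L. Interferon-stimulated genes rose and proliferation genes fell. Most endothelial, fibroblast, epithelial and MHC class I genes also rose and most macrophage and neutrophil genes fell, but as lists these were not called with an estimated correlation (adjusted p = 0.0844, 0.0950, 0.215, 0.0844 and 0.0844 in that order). Cox4i2, a lung and smooth muscle subunit of cytochrome c oxidase (chromosome 2, 152754173 to 152765037), rose (24.3 ± 0.329 against 1.65 ± 0.229 RPKM; log2 fold change 3.26, SE 0.0676, adjusted p = 2.67e-07). Arg1, the arginase of alternatively activated macrophages (chromosome 10, 24915221 to 24927484), had 6.54 ± 0.427 against 28.3 ± 1.15 RPKM (SD, n = 2; log2 fold change -1.96, SE 0.0484, adjusted p = 4.14e-07 by limma). Of 13 T cell identity genes, 11 rose and 1 fell, and the list was not called with an estimated correlation (adjusted p = 0.206). Cd8a had 12.8 ± 0.717 against 9.32 ± 0.647 RPKM (log2 fold change 0.42, SE 0.0703, adjusted p = 0.00231) and Gzmb, the cytotoxic protease granzyme B, had 12.5 ± 0.891 against 7.10 ± 0.190 RPKM (log2 fold change 0.74, SE 0.0711, adjusted p = 0.000153). Ifng changed by 0.42 (adjusted p = 0.0118) and Prf1 by 0.29 (adjusted p = 0.0179), and Ccl7 had 5.41 ± 0.0148 against 6.42 ± 0.660 RPKM, which did not pass (adjusted p = 0.171).

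In that comparison, 19 rose and 1 fell of 20 endothelial and fibroblast markers, with 19 and 1 adjusted over the list alone and a median log2 fold change of 1.30 (camera adjusted p = 8.71e-10, adjusted p = 0.0844 with an estimated correlation). Tek, the angiopoietin receptor, changed by 2.18, Pecam1 by 1.73 and Cdh5, the endothelial cadherin, by 2.07. Of 23 epithelial and tumour markers, 20 rose and 3 fell (20 and 3 adjusted over the list alone, median 0.87, camera adjusted p = 2.37e-06, adjusted p = 0.0950 with an estimated correlation), with Sftpc at 1.13 and Ager, a marker of alveolar type I cells, at 1.60. Of 40 interferon-stimulated genes, 31 rose and 4 fell (31 and 4 adjusted over the list alone, median 0.48), a call that held with an estimated correlation (adjusted p = 0.0367). Gbp2 changed by 1.31, Igtp by 1.22 and Ifit3b by 1.50. In MHC class I presentation, 17 rose and 0 fell of 18 (17 and 0 adjusted over the list alone; camera adjusted p = 3.41e-05, adjusted p = 0.215 with an estimated correlation), with Irf1, an interferon-gamma-induced transcription factor, at 1.18. In T cell identity, 11 rose and 1 fell of 13 (11 and 1 adjusted over the list alone, median 0.25; camera adjusted p = 0.0338, adjusted p = 0.206 with an estimated correlation). Cd3g changed by 0.46 and Cd2, the gene that fell, by -0.72.

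Macrophage and monocyte markers gave the opposite direction, 0 rose and 18 fell of 22 (0 and 20 adjusted over the list alone, median -0.92, camera adjusted p = 2.37e-09, adjusted p = 0.0844 with an estimated correlation), with Mrc1, the mannose receptor, at -1.45 and Cd68, a lysosomal protein of macrophages, at -1.27. Of 14 neutrophil markers, 0 rose and 14 fell (0 and 14 adjusted over the list alone, median -0.84; camera adjusted p = 5.17e-07, adjusted p = 0.0844 with an estimated correlation). Of 44 proliferation genes, 1 rose and 35 fell (1 and 37 adjusted over the list alone, median -0.36), and the call held with an estimated correlation (adjusted p = 0.0367). Mki67 changed by -0.75 and Bub1b, a spindle checkpoint kinase, by -0.91. Of 18 B and plasma cell markers, 4 rose and 13 fell (4 and 13 adjusted over the list alone; camera adjusted p = 0.00810, adjusted p = 0.299 with an estimated correlation), where the B cell factor Pax5 changed by -1.04 and the light chain gene Iglc1 by 0.96. Of 21 glycolysis genes, 3 rose and 13 fell (3 and 14 adjusted over the list alone; camera adjusted p = 0.00537, adjusted p = 0.396 with an estimated correlation).
The 14 lists that camera did not call included cytotoxic effectors (10 rose and 4 fell of 21, adjusted p = 0.263), where Tnf changed by -1.20 and Ccl3 by -1.03. They also included inhibitory receptors and exhaustion (8 rose and 9 fell of 20, adjusted p = 0.399), where Pdcd1, which encodes PD-1, changed by 0.80 and Havcr2 by -1.08. Tissue residency genes split into 4 rose and 6 fell of 14 (adjusted p = 0.505), with Itga1 at 1.77 and Bhlhe40 at -0.97. NK and gamma-delta T cell markers gave 3 rose and 2 fell of 10 (adjusted p = 0.692). Immediate early and heat shock genes gave 15 rose and 8 fell of 28 (adjusted p = 0.120), including Egr1 at 1.15. Other large rises were Gucy1b3, a soluble guanylate cyclase subunit, at 2.75, Inmt at 2.68, Ppp1r14a, an inhibitor of smooth muscle myosin phosphatase, at 2.63, and the matrix protein gene Postn at 2.54. Other large falls were Rnase2a, an eosinophil-type ribonuclease gene, at -1.90, Gdf15 at -1.71, Fabp1 at -1.66, Chil3, a chitinase-like protein gene, at -1.56 and Gpnmb at -1.54.

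Over all genes, 9160 of 15868 changed, 4845 up and 4315 down, and 1154 changed at least 2-fold. The groups did not overlap for 78.6% of genes, where chance gives 1 in 3. The count was 5961 of the 8753 genes with at least 5 RPKM in at least 2 libraries, and the 2-fold count was 2010 with a pseudocount of 0.1 and 435 with a pseudocount of 5.

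PD-1Ab7 was compared with PBS in the same way. Epithelial and interferon-stimulated genes rose, and neutrophil and cytotoxic effector genes fell, while the T cell identity list was not called. Sftpc (chromosome 14, 70520949 to 70524081) had 1940 ± 44.2 against 823 ± 11.5 RPKM (SD, n = 2; log2 fold change 1.24, SE 0.0263, adjusted p = 8.05e-06 by limma). S100a8, a calprotectin subunit of neutrophils (chromosome 3, 90668978 to 90670035), had 46.3 ± 1.38 against 104 ± 6.39 RPKM (log2 fold change -1.15, SE 0.0466, adjusted p = 5.05e-05). Cd8a had 10.5 ± 0.0984 against 9.32 ± 0.647 RPKM (log2 fold change 0.15, SE 0.0703, adjusted p = 0.153), which did not pass the threshold. Pdcd1 rose (log2 fold change 0.49, SE 0.0884, adjusted p = 0.00897). Ifng (-0.14, adjusted p = 0.359), Prf1 (0.02, adjusted p = 0.886) and Ccl7 (-0.02, adjusted p = 0.934) did not pass.

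In that comparison with PBS, 20 rose and 0 fell of 23 epithelial and tumour markers (20 and 0 adjusted over the list alone, median 0.47, adjusted p = 0.0448 with an estimated correlation), with Ager at 1.26 and Lamp3 at 1.06. Of 40 interferon-stimulated genes, 26 rose and 0 fell (31 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.0370 with an estimated correlation), including Gbp2 at 0.66. Of 20 endothelial and fibroblast markers, 17 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.36; camera adjusted p = 4.95e-11, adjusted p = 0.0550 with an estimated correlation). Of 14 neutrophil markers, 0 rose and 13 fell (0 and 14 adjusted over the list alone, median -0.77, adjusted p = 0.0448 with an estimated correlation). Of 21 cytotoxic effectors, 2 rose and 13 fell (2 and 14 adjusted over the list alone, median -0.29, adjusted p = 0.0480 with an estimated correlation), including Gzma at -0.56, Gzmb at -0.32, Tnf at -0.55 and the NK receptor gene Klrk1 at -0.45. Oxidative phosphorylation (21 rose and 0 fell of 72, median 0.10), ribosomal protein (27 rose and 2 fell of 87, median 0.08) and mitochondrially encoded genes (7 rose and 0 fell of 13, median 0.26) shifted upward by small amounts, with adjusted p = 0.205, 0.384 and 0.205 with an estimated correlation. Red cell markers (0 rose and 4 fell of 5), MHC class I presentation (7 rose and 1 fell of 18) and chemokine and cytokine receptors (0 rose and 8 fell of 24) were also called, with adjusted p = 0.205, 0.384 and 0.205 with an estimated correlation. T cell identity (3 rose and 0 fell of 13, camera adjusted p = 0.257), macrophage and monocyte markers (3 rose and 8 fell of 22, adjusted p = 0.117), proliferation (8 rose and 2 fell of 44, adjusted p = 0.373) and CD4 and regulatory T cell markers (0 rose and 2 fell of 9, adjusted p = 0.473) were not called. Large rises outside immunoglobulin segments were Dlk1, a Notch ligand of progenitor cells, at 1.80, Bex4 at 1.76 and Bex2 at 1.74. Nr4a3, an immediate early nuclear receptor, changed by -0.50.

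Over all genes, 4451 changed, 2405 up and 2046 down, 103 of them at least 2-fold. The groups did not overlap for 66.3% of genes. The count fell to 2814 without PBS replicate 1, 2802 without PBS replicate 2 and 2912 without PD-1Ab7 replicate 2, and the 2-fold count was 264 with a pseudocount of 0.1 and 38 with a pseudocount of 5.

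Flt3L plus PD-1Ab7 was compared with PBS to ask what the combination changed. T cell identity genes fell, and epithelial and interferon-stimulated genes rose. Most B cell genes also fell, but as a list they were not called with an estimated correlation (adjusted p = 0.0586). Cd8b1 had 18.2 ± 0.345 against 47.6 ± 0.964 RPKM (SD, n = 2; log2 fold change -1.34, SE 0.0371, adjusted p = 4.21e-06 by limma), Cd8a had 4.44 ± 0.426 against 9.32 ± 0.647 RPKM (log2 fold change -0.93, SE 0.0703, adjusted p = 0.000108) and Cd3e had 3.26 ± 0.323 against 7.55 ± 0.185 RPKM (log2 fold change -1.01, SE 0.0586, adjusted p = 4.02e-05). Slfn4, an interferon-induced gene of myeloid cells (chromosome 11, 83175186 to 83190216), rose (243 ± 3.53 against 49.2 ± 0.0926 RPKM; log2 fold change 2.28, SE 0.0374). Ifng, the interferon of activated T and NK cells, had 0.666 ± 0.171 against 1.63 ± 0.0210 RPKM (log2 fold change -0.66, SE 0.102, adjusted p = 0.00224), and Prf1, which encodes the pore-forming protein perforin, changed by -0.33 (adjusted p = 0.0130). Ccl7 had 6.09 ± 1.01 against 6.42 ± 0.660 RPKM and did not pass (adjusted p = 0.649). Flt3 itself, the receptor of the ligand, had 0.780 ± 0.00676 against 1.07 ± 0.0360 RPKM (log2 fold change -0.21, SE 0.0604, adjusted p = 0.0250).

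In that comparison with PBS, T cell identity gave 0 rose and 13 fell of 13 (0 and 13 adjusted over the list alone, median -0.91, adjusted p = 0.0286 with an estimated correlation). Naive, memory and stem-like genes gave 2 rose and 15 fell of 20 (2 and 16 adjusted over the list alone, median -0.72; camera adjusted p = 1.48e-05, adjusted p = 0.0978 with an estimated correlation), with Tcf7, the factor of stem-like T cells, at -1.19 and Il7r at -0.86. Costimulation genes gave 1 rose and 10 fell of 16 (2 and 11 adjusted over the list alone, adjusted p = 0.0849 with an estimated correlation), with Cd27 at -1.24. Cytotoxic effectors gave 4 rose and 12 fell of 21 (4 and 13 adjusted over the list alone, median -0.29, adjusted p = 0.0978 with an estimated correlation), with Gzmb at -0.30. Inhibitory receptors and exhaustion gave 4 rose and 11 fell of 20 (4 and 11 adjusted over the list alone, adjusted p = 0.214 with an estimated correlation), with Ctla4 at -0.75, and Pdcd1 at -0.13 did not pass (adjusted p = 0.275). B and plasma cell markers gave 0 rose and 17 fell of 18 (0 and 17 adjusted over the list alone, median -0.84; camera adjusted p = 1.88e-10, adjusted p = 0.0586 with an estimated correlation), with Cd19 at -1.04 and Ighd at -1.29. Ribosomal protein genes gave 7 rose and 71 fell of 87 (8 and 73 adjusted over the list alone, median -0.27; camera adjusted p = 9.87e-13, adjusted p = 0.121 with an estimated correlation). Dendritic cell and MHC class II markers gave 4 rose and 14 fell of 21 (4 and 14 adjusted over the list alone, median -0.29, adjusted p = 0.0801 with an estimated correlation), with H2-Ab1 at -0.48, and red cell markers gave 0 rose and 5 fell of 5 (0 and 5 adjusted over the list alone, adjusted p = 0.0978 with an estimated correlation).

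Among lists that rose with Flt3L plus PD-1Ab7 against PBS, epithelial and tumour markers gave 23 rose and 0 fell of 23 (23 and 0 adjusted over the list alone, median 1.14, adjusted p = 0.0286 with an estimated correlation), with Krt18 at 1.60 and Sftpd at 1.33. Interferon-stimulated genes gave 32 rose and 1 fell of 40 (33 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0286 with an estimated correlation), with Ifit3 at 1.41. Endothelial and fibroblast markers gave 17 rose and 1 fell of 20 (17 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.0801 with an estimated correlation). Neutrophil markers gave 9 rose and 2 fell of 14 (9 and 3 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with S100a8 at 0.86 and Ltf, a granule protein gene, at -0.73. Glycolysis genes gave 12 rose and 5 fell of 21 (12 and 6 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation). Macrophage and monocyte markers (4 rose and 12 fell of 22, camera adjusted p = 0.0707) and NK and gamma-delta T cell markers (1 rose and 4 fell of 10, adjusted p = 0.302) were not called. Other large rises were Spink5, a serine protease inhibitor gene, at 3.13, Apoc1 at 2.52, the acute phase gene Saa3 at 2.47, Gkn2 at 2.23 and Serpina3n at 1.88.

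Over all genes, 7875 changed, 3856 up and 4019 down, 397 of them at least 2-fold, and the groups did not overlap for 76.6% of genes. The 2-fold count was 1001 with a pseudocount of 0.1 and 93 with a pseudocount of 5.

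**Figure D2:**
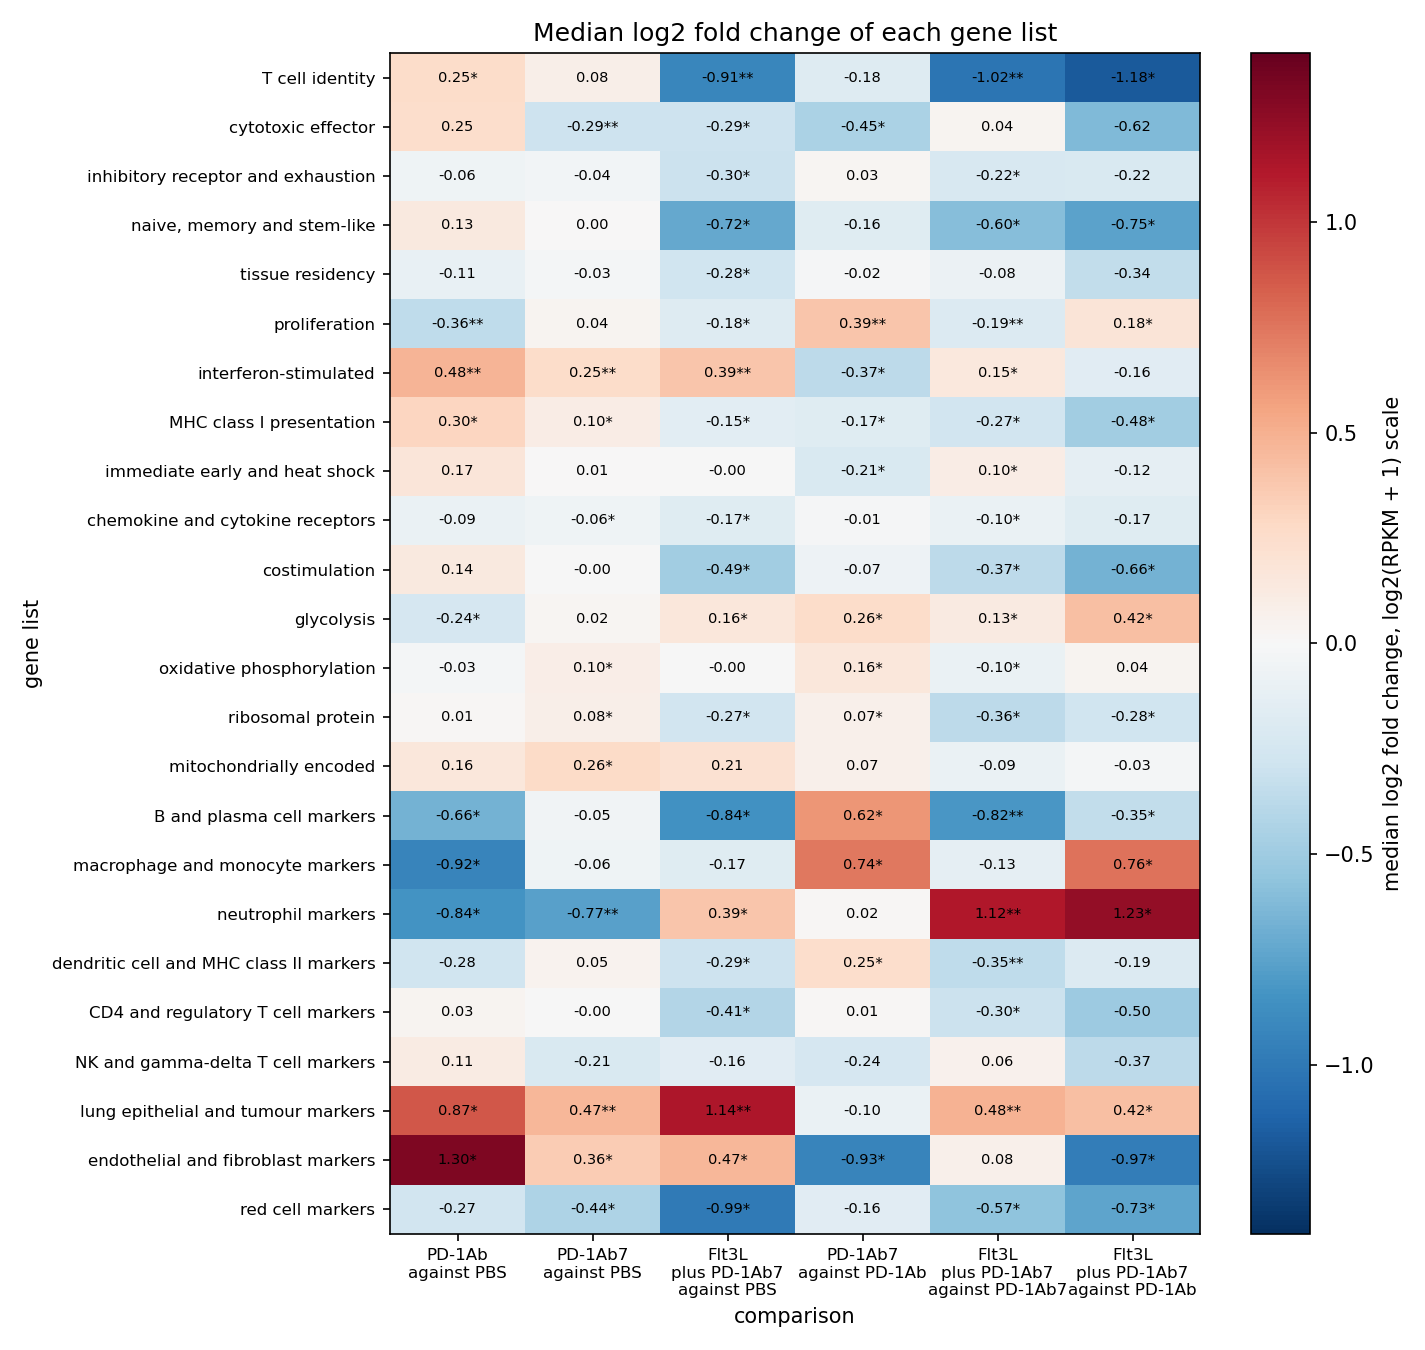
Median log2 fold change of each of the 24 gene lists in each of the 6 comparisons, on the log2(RPKM + 1) scale. One asterisk marks a camera call at a preset correlation and a second a call that also held with an estimated correlation. T cell identity has medians of -0.91, -1.02 and -1.18 in the 3 comparisons of Flt3L plus PD-1Ab7.

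PD-1Ab7 was compared with PD-1Ab with no knowledge from the labels of how they differ. Proliferation genes were higher with PD-1Ab7. Most macrophage genes were also higher and most endothelial and fibroblast genes lower, but neither list was called with an estimated correlation (adjusted p = 0.0813 and 0.0813). Mki67 had 51.6 ± 0.469 against 32.1 ± 1.18 RPKM (SD, n = 2; log2 fold change 0.67, SE 0.0295, adjusted p = 6.22e-06 by limma). Gzmb had 5.47 ± 0.344 against 12.5 ± 0.891 RPKM (log2 fold change -1.06, SE 0.0711, adjusted p = 3.75e-05) and Arg1 changed by 2.25. Proliferation genes gave 38 rose and 0 fell of 44 (40 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.0314 with an estimated correlation). Macrophage and monocyte markers gave 20 rose and 0 fell of 22 (20 and 0 adjusted over the list alone, median 0.74; camera adjusted p = 1.81e-10, adjusted p = 0.0813 with an estimated correlation), with Mrc1 at 1.27 and Cd68 at 1.18. Endothelial and fibroblast markers gave 0 rose and 18 fell of 20 (0 and 18 adjusted over the list alone, median -0.93, adjusted p = 0.0813 with an estimated correlation), with Tek at -1.84. Interferon-stimulated genes gave 5 rose and 24 fell of 40 (5 and 25 adjusted over the list alone, median -0.37, adjusted p = 0.0813 with an estimated correlation), with Igtp at -0.81. Cytotoxic effectors gave 3 rose and 14 fell of 21 (3 and 15 adjusted over the list alone, median -0.45, adjusted p = 0.148 with an estimated correlation), with Klrc1 at -1.22 and Ccl3 at 0.74. T cell identity gave 1 rose and 7 fell of 13 and was not called (camera adjusted p = 0.0698). Oxidative phosphorylation gave 38 rose and 0 fell of 72 (38 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.166 with an estimated correlation).
Other large rises were Rnase2a at 2.43, Mucl1 at 2.03 and the macrophage elastase Mmp12 at 1.98, and large falls were Cox4i2 at -2.80 and Gucy1b3 at -2.26. Over all genes, 8120 changed, 3885 up and 4235 down, 741 of them at least 2-fold. The 2-fold count was 1424 with a pseudocount of 0.1 and 254 with a pseudocount of 5.

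Flt3L plus PD-1Ab7 was compared with PD-1Ab7 to ask what Flt3L added. Neutrophil and epithelial genes rose, and T cell identity, B and plasma cell, and dendritic cell and MHC class II markers fell. S100a8 had 190 ± 5.99 against 46.3 ± 1.38 RPKM (SD, n = 2; log2 fold change 2.01, SE 0.0466, adjusted p = 5.67e-06 by limma), S100a9 (chromosome 3, 90692632 to 90695721) changed by 2.19 and Slfn4 by 3.11. Cd8b1 had 18.2 ± 0.345 against 50.5 ± 1.70 RPKM (log2 fold change -1.42, SE 0.0371, adjusted p = 5.67e-06). Gzmb had 5.57 ± 0.478 against 5.47 ± 0.344 RPKM (log2 fold change 0.02, SE 0.0711, adjusted p = 0.845) and did not pass the threshold. T cell identity gave 0 rose and 13 fell of 13 (0 and 13 adjusted over the list alone, median -1.02, adjusted p = 0.0322 with an estimated correlation), with Itk at -1.17. Neutrophil markers gave 12 rose and 1 fell of 14 (12 and 1 adjusted over the list alone, median 1.12, adjusted p = 0.0394 with an estimated correlation), with Cxcr2 at 1.44. Epithelial and tumour markers gave 21 rose and 0 fell of 23 (22 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.0324 with an estimated correlation), with Krt18 at 1.07. B and plasma cell markers gave 0 rose and 17 fell of 18 (0 and 17 adjusted over the list alone, median -0.82, adjusted p = 0.0394 with an estimated correlation), with Ighd at -1.35. Dendritic cell and MHC class II markers gave 1 rose and 15 fell of 21 (1 and 16 adjusted over the list alone, median -0.35, adjusted p = 0.0324 with an estimated correlation), with H2-Aa at -0.47. The list joins dendritic cell genes with MHC class II genes, so its fall need not be one of dendritic cells. The cDC1 receptor Clec9a had 9.22 ± 0.215 RPKM against 7.97 ± 0.0292 in PD-1Ab7, 6.98 ± 0.145 in PBS and 18.55 ± 0.62 in PD-1Ab. Xcr1, under 1 RPKM, had 0.436 ± 0.112 against 0.716 ± 0.0942 RPKM in PD-1Ab7 (SD, n = 2). Proliferation genes gave 1 rose and 24 fell of 44 (1 and 30 adjusted over the list alone, median -0.19, adjusted p = 0.0322 with an estimated correlation).
Ribosomal protein genes gave 1 rose and 76 fell of 87 (1 and 78 adjusted over the list alone, median -0.36; camera adjusted p = 1.13e-24, adjusted p = 0.0703 with an estimated correlation). Other large rises were Spink5 at 2.88, Ly6g, a neutrophil surface antigen gene, at 1.94, Il1f9 at 1.93 and Stfa2l1 at 1.88, and large falls were Alox15, a lipoxygenase gene, at -2.19, Prg4 at -2.00 and Glycam1 at -1.96. Over all genes, 5657 changed, 2847 up and 2810 down, 260 of them at least 2-fold. The 2-fold count was 545 with a pseudocount of 0.1 and 74 with a pseudocount of 5.

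Flt3L plus PD-1Ab7 was compared with PD-1Ab, a contrast that joins Flt3L with whatever sets PD-1Ab7 apart from PD-1Ab. Most macrophage and neutrophil genes were higher and most endothelial, T cell and MHC class I genes lower, but no list was called with an estimated correlation (adjusted p = 0.0859, 0.0859, 0.0859, 0.0859 and 0.159 in that order). Arg1 had 53.7 ± 0.726 against 6.54 ± 0.427 RPKM (SD, n = 2; log2 fold change 2.86, SE 0.0484, adjusted p = 8.45e-07 by limma) and Cd8b1 had 18.2 ± 0.345 against 60.8 ± 2.03 RPKM (log2 fold change -1.69, SE 0.0371, adjusted p = 8.94e-07). T cell identity gave 1 rose and 12 fell of 13 (1 and 12 adjusted over the list alone, median -1.18; camera adjusted p = 2.44e-06, adjusted p = 0.0859 with an estimated correlation). Macrophage and monocyte markers gave 20 rose and 1 fell of 22 (20 and 1 adjusted over the list alone, median 0.76, adjusted p = 0.0859 with an estimated correlation), with Cd14 at 1.42. Neutrophil markers gave 12 rose and 1 fell of 14 (12 and 1 adjusted over the list alone, median 1.23, adjusted p = 0.0859 with an estimated correlation). Endothelial and fibroblast markers gave 0 rose and 20 fell of 20 (0 and 20 adjusted over the list alone, median -0.97, adjusted p = 0.0859 with an estimated correlation), with Tek at -1.53. MHC class I presentation gave 0 rose and 17 fell of 18 (0 and 17 adjusted over the list alone, median -0.48, adjusted p = 0.159 with an estimated correlation), with Irf1 at -1.16. Glycolysis genes gave 17 rose and 3 fell of 21 (17 and 3 adjusted over the list alone, median 0.42, adjusted p = 0.193 with an estimated correlation), with Slc16a3, a lactate transporter gene, at 1.15. Other large rises were Slfn4 at 3.02, Rnase2a at 2.76, Spink5 at 2.54, Apoc1 at 2.09 and Gkn2 at 1.99.
Over all genes, 9402 changed, 4223 up and 5179 down, 823 of them at least 2-fold. The count was 6135 of the 8753 genes with at least 5 RPKM in at least 2 libraries, and the 2-fold count was 1543 with a pseudocount of 0.1 and 287 with a pseudocount of 5.

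**Figure D3:**
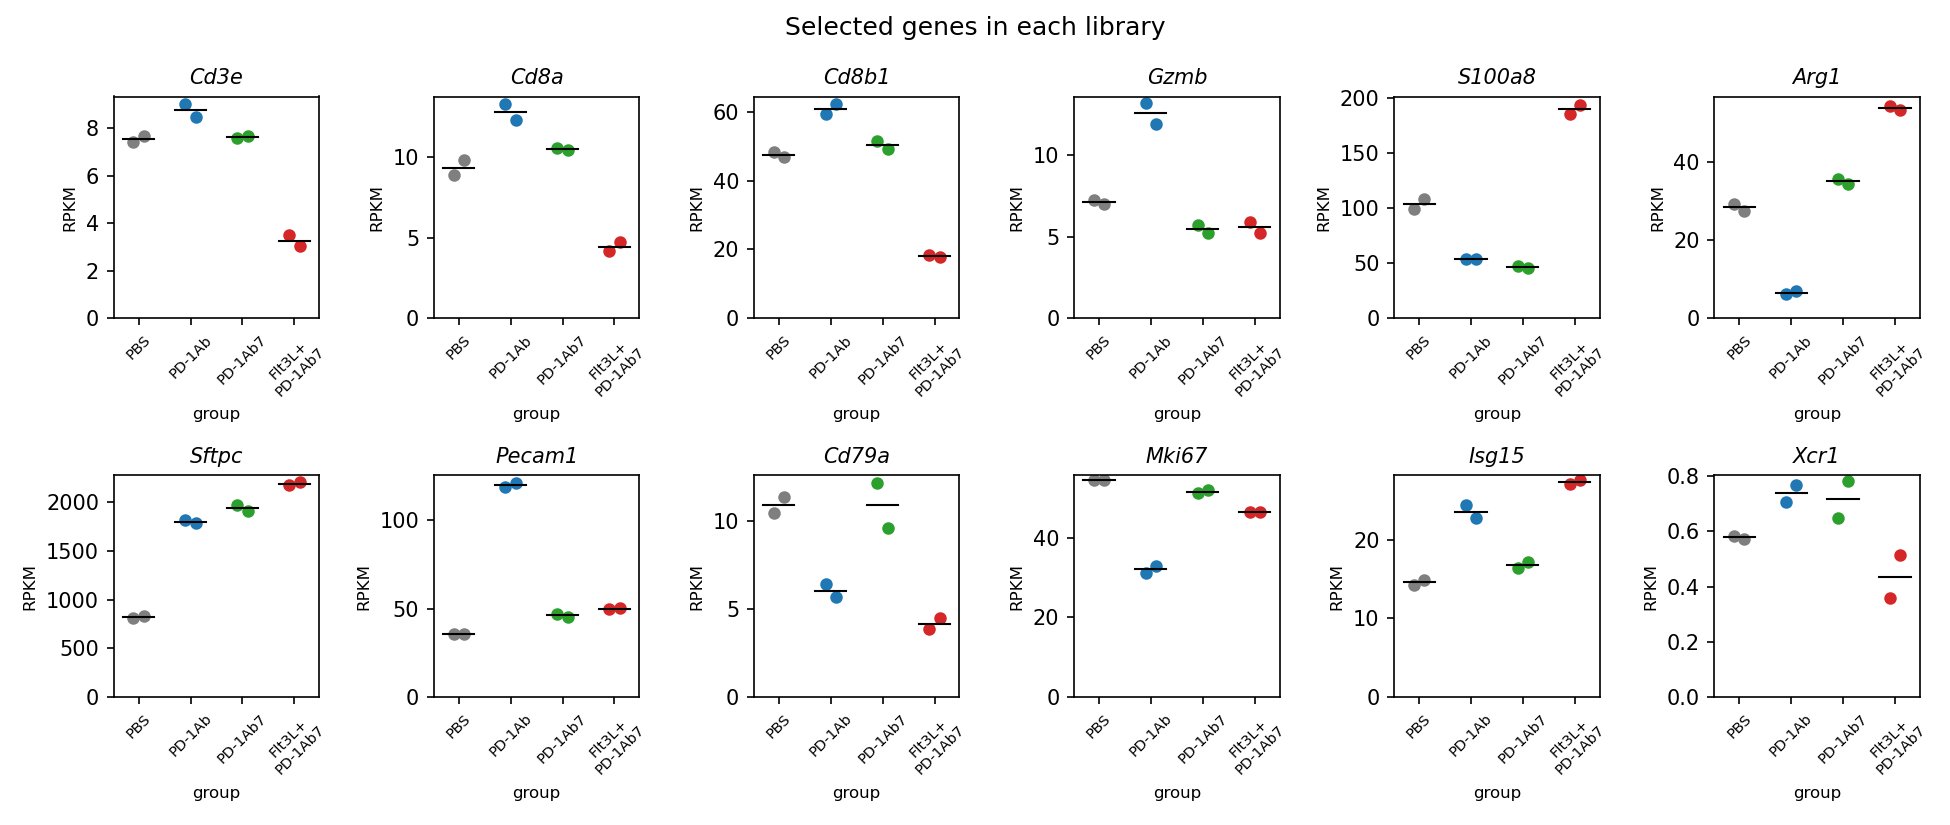
RPKM of 12 genes in each library by treatment, with a point per library and a line at the group mean of 2 libraries; each axis starts at 0. Cd8b1 lies at 17.9 to 62.3 RPKM over the 8 libraries with its lowest values in Flt3L plus PD-1Ab7, and S100a8 has its highest values there.

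Immunoglobulin V segments were among the 20 largest changes in each comparison. Ighv9-1 had 79.3 ± 0.289 against 6.77 ± 0.719 RPKM in PD-1Ab against PBS (SD, n = 2; log2 fold change 3.37, SE 0.0585) and 131 ± 2.88 against 6.77 ± 0.719 RPKM in PD-1Ab7 against PBS. Ighv1-7 changed by -3.03 in PD-1Ab7 and -3.02 in Flt3L plus PD-1Ab7 against PBS, and Ighv10-1 by -3.47 in Flt3L plus PD-1Ab7 against PD-1Ab. Some segments of a family are similar in sequence, so reads may be shared between them and single segments are uncertain.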

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

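The 2-fold counts and the limma-voom fit were chosen after seeing the data; the other alternatives were planned. If the recovered 47770550 to 58539981 reads per library hold, depth limits only low genes. Of the values of named genes under alternatives, 13918 kept their direction and side of the threshold, 43 newly passed, 250 no longer passed and 3 reversed; for lists the numbers were 2623, 29, 84 and 0. The reversed values came from quantile normalization: mt-Nd6 changed by -0.00539 in Flt3L plus PD-1Ab7 against PBS and -0.15 against PD-1Ab, and mt-Nd4 by 0.0421 against PD-1Ab7; the cause was not tested.

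Counts of changed genes stayed within 1.5 times of those reported under other pseudocounts, scalings, the robust prior, fits of 2 groups and no filter. With at least 5 RPKM required in at least 2 libraries, 5961 genes changed in PD-1Ab against PBS and 6135 in Flt3L plus PD-1Ab7 against PD-1Ab, because fewer genes (8753) were tested. Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 7855 to 9084 genes for PD-1Ab against PBS, 5987 to 7677 for Flt3L plus PD-1Ab7 against PBS, 6655 to 7939 for PD-1Ab7 against PD-1Ab, 3865 to 5326 for Flt3L plus PD-1Ab7 against PD-1Ab7 and 7851 to 9262 against PD-1Ab. For PD-1Ab7 against PBS it gave 2802 to 4087, with 2814 without PBS replicate 1, 2802 without PBS replicate 2 and 2912 without PD-1Ab7 replicate 2. With the replicate number as a replicate block the counts were 8938, 3889, 7459, 7812, 5176 and 9134 in the order of the report. Same-numbered libraries did not deviate together (correlations -0.044 to 0.057), so no shared shift followed the numbers. Pairing of samples without such a shift cannot be excluded. The limma-voom fit on reads recovered from RPKM called 7751, 4542, 6793, 7078, 5353 and 7938 of 12800 genes.

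The 2-fold counts depended on the pseudocount, by construction of the log scale for low genes. In the same order they were 2010, 264, 1001, 1424, 545 and 1543 with a pseudocount of 0.1, and 435, 38, 93, 254, 74 and 287 with 5. With limma-voom they were 1749, 287, 959, 1240, 510 and 1386. Rescaled to an equal sum per library (TPM), they were 174 for PD-1Ab7 and 731 for Flt3L plus PD-1Ab7 against PBS, 1143 for PD-1Ab7 against PD-1Ab and 406 for Flt3L plus PD-1Ab7 against PD-1Ab7. The RPKM sums were 365200 to 375634, and the rescaling raised all of them to a larger sum. The pseudocount stayed 1, so the rescaling acted as a smaller pseudocount does. The number of lists called fell with an estimated correlation from 10, 11, 19, 12, 18 and 13 to 2, 4, 3, 1, 6 and 0. Without a filter on low values it was 16 for PD-1Ab against PBS. A larger correlation does not account for the weaker result of every list. In Flt3L plus PD-1Ab7 against PBS, T cell identity had an estimated correlation of -0.052, below the preset 0.01. Its camera p still went from 2.06e-10 to 0.00254. Proliferation, with an estimated correlation of -0.015, went from a camera p of 0.000185 to 0.0111. The 2 forms of camera also differ in their degrees of freedom. With an estimated correlation, camera refers to the 4 residual degrees of freedom of the fit. At a preset correlation it refers to a far larger number set by the genes tested. The share of the weakening due to this, and why the filter mattered, was not tested.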

Other observations

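All tests in this part were chosen after the result was seen, except the test of T cell genes outside the T cell identity list, and the scalings used in another test were planned. Further values not described above concern markers of sex and of T cell state. Xist, transcribed from the inactive X chromosome, and Ddx3y, a Y-linked gene, were both detected in all 8 libraries. They lay at 13.55 to 19.95 and 12 to 17.49 RPKM, and Eif2s3y, also Y-linked, at 4.04 to 8.15 RPKM. Female and male transcripts together argue against a library made from a single animal. Their balance differed between treatments, so treatment cannot be told apart from the mix of animals. Xist had 19.6 ± 0.413 RPKM in PBS, 19.3 ± 0.573 in PD-1Ab, 16.7 ± 0.416 in PD-1Ab7 and 13.7 ± 0.245 in Flt3L plus PD-1Ab7 (SD, n = 2), and Ddx3y had 16.0 ± 0.216, 12 ± 0.00272, 14.8 ± 0.2 and 17.4 ± 0.0969 RPKM in the same order. Scgb1a1 of airway club cells had 767 ± 49.3, 3797 ± 208, 1029 ± 25.4 and 2192 ± 107 RPKM in that order. Gm42418, a gene overlapping ribosomal RNA sequence, had 216 and 570 RPKM in the 2 PBS libraries. AY036118 (376 and 985 RPKM) and Lars2 (2.24 and 6.21 RPKM) were also higher in PBS replicate 2. In the PD-1Ab libraries Gm42418 had 178 and 255 RPKM and AY036118 316 and 443 RPKM.

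Relative to the mean of the T cell identity list in the same library, 19 of 21 cytotoxic effector genes, 20 of 20 inhibitory receptor and exhaustion genes and 13 of 20 naive, memory and stem-like genes were higher in Flt3L plus PD-1Ab7 than in PBS by limma, adjusted over these genes, and 0, 0 and 2 were lower. In PD-1Ab7 against PBS, 2 cytotoxic effector genes were higher and 16 lower, against 6 and 8 inhibitory receptor and exhaustion genes and 5 and 9 naive, memory and stem-like genes. This ratio moves with the list's own change, and several of the genes (Tnf, Ccl3, Havcr2, Entpd1) are also expressed by myeloid cells, so it does not measure expression per T cell.

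The libraries labelled CD8+ T cell carried more macrophage than T cell transcripts. The ratio of the median macrophage marker to the median T cell identity gene was between 1.87 and 9.10 over the 8 libraries. The median lung epithelial marker also lay above the median T cell identity gene, by a ratio of 2.26 to 9.04, which argues against sorted T cells with only a small carry-over of other cells. Xcr1 reached at most 0.023 of the median macrophage marker, which argues against a library of sorted cDC1, the cell type the series design text names. That test rests on 1 gene. Clec9a, another cDC1 receptor, came closer to the macrophage marker, with a mean of 18.55 RPKM in PD-1Ab against a median macrophage marker of 34.3. At least 87.5% of the listed markers reached 1 RPKM in at least 2 libraries in each of 5 lists, of macrophages, neutrophils, B cells, epithelium, and endothelium and fibroblasts. RNA of unsorted or weakly enriched tumour-bearing lung would give this and is a candidate explanation. A sort with a large carry-over of other cells would pass this low bar too, so the share does not tell them apart. Whether the sort failed or another material was sequenced was not tested.

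All 13 T cell identity genes were lower in Flt3L plus PD-1Ab7 than in PBS and PD-1Ab7, and 12 of 13 than in PD-1Ab, where 1 rose. The median log2 fold change nearest 0 over 3 comparisons and 4 scalings was -0.89, so the fall does not depend on the choice among these scalings. Median-of-ratios factors were only 0.989 to 1.012, so the test could hardly come out otherwise. It does not exclude a fault that these scalings share. Of 10 other T cell genes named before their values were seen, 9 were measured, Sh2d1a being too low, and all 9 fell in each of the 3 comparisons; their medians lay at -0.81, -0.76 and -0.96 and differed from the list's by at most 0.26. A smaller share of T cell RNA in these libraries is thus a candidate explanation. An effect of the treatment on T cell numbers, a difference between the animals used and a difference in tissue sampling stay open, because each group may rest on a single RNA pool.

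The 2 libraries of each group differed little, with a spread beyond counting error of 1.37% to 3.05% over genes of high depth, though the mean chi-squared per gene was 1.49 to 2.83 where counting error alone gives 1, and Gm42418 differed more in PBS. Over 111 immunoglobulin V segments with a mean of at least 5 RPKM, the SD within groups was 0.14 and between group means 0.81 on the log2 scale, a ratio of 0.17, so a shared pool of RNA for both libraries of a group is a candidate explanation. The deviations of the 2 libraries from the other groups correlated across segments at 0.963 to 0.983, but both deviations subtract the same mean, so this decides nothing about separate animals. Xist and Ddx3y, both present in every library, argue against a single animal in each. Separate sets of animals in which a treatment shifts V segment use alike stay open.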
